A study of Mus musculus with 6 samples.

How the data were processed

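RNA was sequenced from N2a cells, a mouse neuroblastoma line, that had been differentiated with retinoic acid (10 µM for 96 h in medium with 2% serum). Per the labels, 3 libraries came from cells given the solvent DMSO and 3 from cells given RSL3, an inhibitor of the glutathione peroxidase GPX4 that induces ferroptosis, at 5 µM for 24 h. Whether the 3 libraries of a group came from separate cultures grown on separate days is not given in the sources used here. The p-values of single RNAs therefore measure a difference against the spread between the 3 libraries of each group. Those of the list test camera compare the genes of a list with all other genes, and those for circRNAs against host genes permute the circRNAs. The labels number the libraries of each group but state no pairing. The gene-wise deviations of same-numbered libraries from their group means correlated across genes at -0.15, 0.05 and -0.06, so the numbers were not used as pairs, and a fit with the number as a block was run as an alternative.

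There were 18 tables, 3 for each library. The deposited mRNA and lncRNA values are in FPKM, and the authors' processing notes name cutadapt, HISAT2, StringTie 1.3.3 and the mouse build GRCm38. The library protocol names a poly(A) selection module under the removal of ribosomal RNA, and a stranded kit. The annotation release that the authors used, the circRNA caller and the filters on low values are not given in the sources used here. There were 11609 mRNA genes and 866 lncRNA genes, and in every one the larger of the group means was at least 0.500. Read depth cannot be recovered from FPKM and is unknown for mRNA and lncRNA, so no counting interval is given for them. The deposited circRNA values carry a CPM heading and were recorded here as a signal, because their column sums differ and only the geometric mean of these sums equals 1e+06. Divided by the smallest value of its library, 100% of the circRNA values above 0 lay within 0.01 of a whole number, and these whole numbers were taken as back-splice reads. The circRNA table held 3168 circRNAs, each with at least 3 reads over the 6 libraries, and a library in which one was not seen counts as 0.

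Gene positions, transcript lengths and GC content came from GENCODE M21, in which 11595 of the 11609 mRNA identifiers and 853 of the 866 lncRNA identifiers were found. Of the circRNAs, 1414 were named by coordinates and 1754 by a circBase identifier. With the start counted from 0, both ends of all 1414 fell on exon ends of a single gene, and 1402 matched exactly 1 gene. Starts are printed here counted from 1.

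RSL3 was compared with DMSO in limma 3.58.1 (R 4.3.3) with a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment within each kind of RNA and a threshold of 0.05. For mRNA the test used log2(FPKM + 1) of genes with at least 1 FPKM in at least 3 of the 6 libraries. For lncRNA it used log2(FPKM + 0.5) of genes with at least 0.5 FPKM in at least 3 libraries. For circRNA it used log2 of CPM plus 140, the median over libraries of the smallest value above 0, for circRNAs above 0 in at least 3 libraries. Fold changes of mRNA and lncRNA are given on these log2 scales with the standard error (SE) of the fit, and FPKM as means ± SD of 3 libraries. The number of circRNAs seen per library was compared by an exact permutation test, two-sided, whose smallest possible p with 3 against 3 is 0.1. A count test of the recovered circRNA reads in edgeR 4.0.16 (quasi-likelihood) was an alternative.

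Before the data were examined, 36 gene lists were written down for ferroptosis, stress responses, metabolism, the cell cycle, neuronal identity, RNA preparation and markers of other cell types. The 31 lists with at least 5 tested members were tested with camera of limma at a preset correlation of 0.01, adjusted over the 31 lists. Each list was tested again with a correlation estimated from the data and with fry, whose directional p asks whether the members move one way on balance and whose mixed p asks whether they change in either direction. Members that changed were counted with adjustment over all genes and with adjustment over the list alone. A list of 52 well-studied lncRNAs was handled in the same way.

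The genes named were fixed by a rule before the data were examined. Among mRNAs past the threshold, with groups that did not overlap and a mean of at least 5 FPKM in a group, these are the 8 with the largest rise and the 8 with the largest fall. Each list called by camera adds the 4 members with the smallest p, and each other tested list up to 2 that passed. The ferroptosis and iron genes Gpx4, Slc7a11, Acsl4, Tfrc, Hmox1, Chac1, Ptgs2, Fth1, Ftl1 and Ireb2 are always given. For lncRNA and circRNA the rule takes up to 5 per direction among those that pass. Where no circRNA passes, it takes the 3 with the smallest p in each direction. The rule named 98 mRNAs, 0 lncRNAs and 6 circRNAs, of which 2 mRNAs are not used here as single genes; any other gene is said to have been chosen after its values were seen.

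The tests were run on simulated data made from the deposited tables with 200 altered entries at 4 known folds. These were 200 out of 10590 mRNAs, 200 out of 798 lncRNAs and 200 out of 1662 circRNAs. The noise was drawn independently for each entry and library. Deviations that genes share within a library were not simulated, so recovery and false calls in the real data may differ. For mRNA, 8% of the 1.25-fold, 74% of the 1.5-fold and 98% of the 2-fold changes were recovered, with 6 false calls among 145. For lncRNA the shares were 12%, 54% and 94%, with 5 false calls among 134. The Benjamini-Hochberg adjustment recovers more when a larger share of entries is altered, so recovery would be lower where few lncRNAs change. For circRNA, 0% of 1.5-fold, 2% of 2-fold and 14% of 4-fold changes were recovered, with 0 false calls among 8.

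The alternatives were other pseudocounts, no filter or a stricter filter on low values, median-ratio scaling, quantile normalization (not for circRNA), a fit without the variance trend, the replicate block, other thresholds, the other set tests, the edgeR test, and leaving out each library in turn. Chosen only after seeing the data were fits without liver-type or histone genes, the thinning of circRNA reads to the smallest library, the removal of transcript length and GC trends from each library, and the lists of liver transcripts, lysosomal hydrolases, noradrenergic genes, ribosome biogenesis and histone variants. The correlation of circRNA and host gene changes was planned for tables that name the host gene; these do not, so it was run by coordinates only. No library was left out of the comparisons, and 1019 mRNAs and 68 lncRNAs under the filters were not tested.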

Results

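The transcriptome of retinoic acid-differentiated N2a cells was compared between 3 libraries from cells given DMSO and 3 from cells given RSL3, a compound that blocks the lipid peroxide-reducing enzyme GPX4. The comparison asks which messenger, long non-coding and circular RNAs change when ferroptosis is induced in neuron-like cells. The summed mRNA values of the DMSO libraries were 225295, 224970 and 220605 FPKM, and those of the RSL3 libraries 200135, 213765 and 211874 FPKM. The back-splice reads behind the circRNA values numbered 9409, 7194 and 7179 in the DMSO libraries and 5226, 7364 and 6782 in the RSL3 libraries.

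Across the tested mRNAs the mean pairwise correlation of libraries was 0.991 within DMSO, 0.981 within RSL3 and 0.978 between the groups; genes are not independent replicates. The first principal component held 47.2% of the variance. It placed RSL3 replicate 1 at 26.2, RSL3 replicates 2 and 3 at 1.2 and 7.35, and the DMSO libraries between -13.2 and -9.46. Across genes, the difference of an RSL3 library from the other 2 correlated with the GC content of the transcripts at 0.64, -0.60 and -0.23 for replicates 1, 2 and 3. These 3 differences sum to 0, so their signs are not separate results. Gm26917 (chromosome 17, 39843013 to 39846341, plus strand) and Gm42418 (39846958 to 39848788) are lncRNAs that overlap ribosomal RNA sequence, chosen after their values were seen. Together they reached 20971 ± 2098 FPKM with DMSO and 29856 ± 3245 FPKM with RSL3 (SD, n = 3; exact permutation p = 0.1, the smallest possible). Transcripts typical of liver, a list chosen after its genes were seen, summed to 169 ± 23.7 FPKM with DMSO and 76.9 ± 11 FPKM with RSL3 (SD, n = 3). No p is given for this sum, since the list was chosen for its falls. Mitochondrially encoded mRNAs made up 5.84% ± 0.43 of the mRNA values with DMSO and 5.04% ± 1.17 with RSL3 (SD, n = 3; exact permutation p = 0.3).

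At camera's preset correlation, lists of antioxidant response genes were called higher with RSL3, and of histone, mitotic and transmitter identity genes lower. None of these 4 calls held with an estimated correlation (adjusted p = 0.165, 0.225, 0.225 and 0.254). Of 10590 tested mRNAs, 676 passed at an adjusted p under 0.05 in limma, 261 higher and 415 lower with RSL3. An unadjusted p under 0.05 was reached by 2555. Most changes were small: 8 genes rose and 43 fell by at least 2-fold on the log2(FPKM + 1) scale. That scale shrinks the changes of genes with low values. Among the genes that fell were all 17 tested members of the major urinary protein (Mup) family (median log2 fold change -1.59). A further 20 were among 25 tested liver-type genes (median -1.02). Both sets were chosen after their values were seen. The groups did not overlap for 33% of the tested genes, where chance gives 10%. The median log2 fold change was -0.031, and after quantile normalization 350 genes were higher and 329 lower. Left out 1 at a time, DMSO replicates 1, 2 and 3 gave 165, 143 and 137 genes, and RSL3 replicates 1, 2 and 3 gave 1276, 725 and 187. Of the 77 genes named by the rule that passed, 30 passed in all 6 of these fits. That 0 turned direction tests little, since these genes were picked for passing in the same libraries.

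Srxn1 and Nqo1 rose most among the NRF2 targets, genes that the oxidative stress factor NRF2 switches on. Srxn1 (ENSMUSG00000032802.8, chromosome 2, 152105516 to 152111376, plus strand) repairs overoxidised peroxiredoxins. It rose 2.52-fold, from 9.96 ± 0.46 to 25.1 ± 0.29 FPKM (adjusted p = 0.00148). Nqo1 (ENSMUSG00000003849.8, chromosome 8, 107388225 to 107403206, minus strand), a quinone reductase, rose from 7.27 ± 0.15 to 19.2 ± 2.73 FPKM (log2 fold change 1.28 ± 0.10 SE, adjusted p = 0.00273). Of 30 NRF2 targets, 14 rose and 0 fell, and 19 rose with adjustment over the list alone. The median log2 fold change was 0.37 (camera adjusted p = 3.15e-14, and adjusted p = 0.165 with an estimated correlation). G6pdx and Pgd, which make NADPH in the pentose phosphate pathway, rose by 0.87 and 0.64 on the log2 scale. Blvrb, a biliverdin reductase, rose by 0.91. The haem-degrading Hmox1 went from 48.4 ± 2.05 to 81.1 ± 6.21 FPKM (0.73 ± 0.07, adjusted p = 0.00401). The ferritin heavy chain gene Fth1 went from 685 ± 22.7 to 1020 ± 36 FPKM (0.57 ± 0.06, adjusted p = 0.00424). For these 7 genes every RSL3 library lay above every DMSO library, as the rule required of Srxn1, Nqo1 and Blvrb. Each of the 7 passed in all 6 fits without a single library. The list median in RSL3 replicates 1, 2 and 3 stood 0.26, 0.41 and 0.44 above the DMSO mean. Without DMSO replicate 1 or without DMSO replicate 3, 9 members rose. In the same RSL3 libraries the liver list was lower and the lncRNAs of the ribosomal RNA locus were 1.42 times as high.

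**Figure D1:**
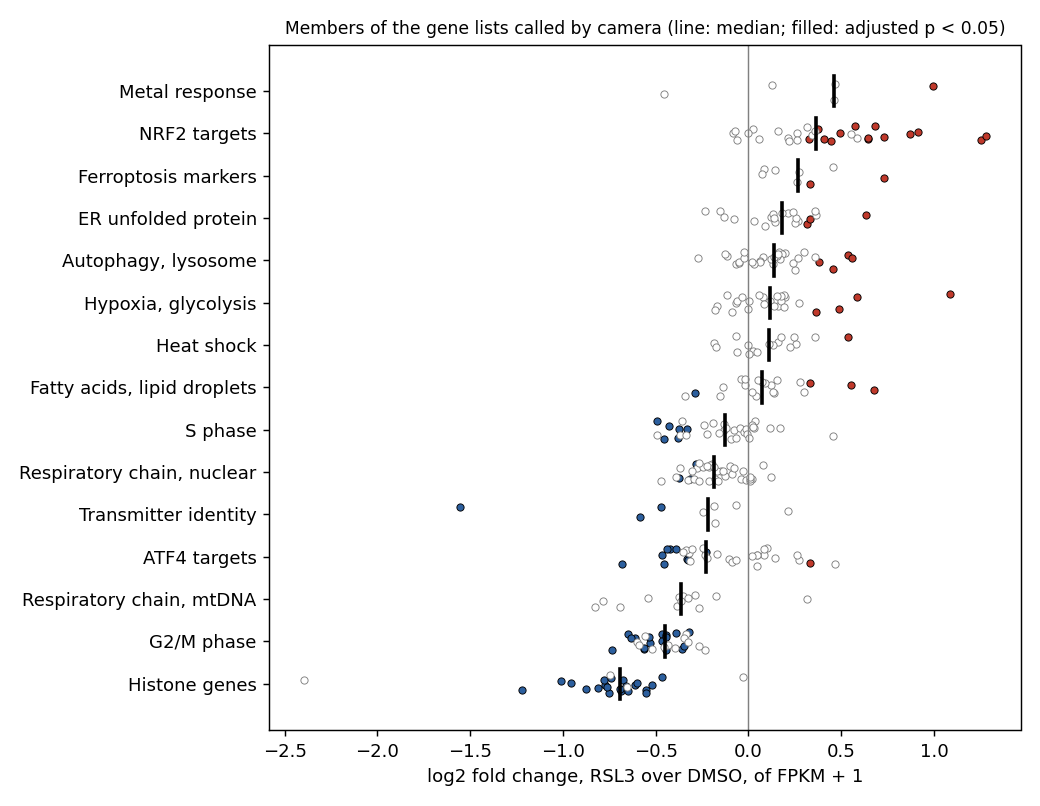
Log2 fold change (RSL3 over DMSO, of FPKM + 1) of each tested member of the 15 gene lists called by camera at the preset correlation, with the median of each list as a line and members with an adjusted p under 0.05 filled. NRF2 targets lie mostly right of 0 (median 0.37) and histone genes left of it (median -0.69).

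The target of RSL3 itself, Gpx4, stood at 158 ± 2.66 FPKM with DMSO and 151 ± 12.6 FPKM with RSL3 (log2 fold change -0.066 ± 0.07, adjusted p = 0.627; 0.093 after quantile normalization). The cystine transporter gene Slc7a11 stood 0.26 ± 0.15 higher (adjusted p = 0.333), the transferrin receptor gene Tfrc 0.27 ± 0.22 (adjusted p = 0.507), and Acsl4, which feeds polyunsaturated lipids into membranes, 0.074 ± 0.18 (adjusted p = 0.847). None of these 3 passed in the main fit. Without RSL3 replicate 1 all 3 did, with log2 fold changes of 0.44 for Slc7a11 (adjusted p = 0.0109), 0.56 for Tfrc (adjusted p = 0.00707) and 0.30 for Acsl4 (adjusted p = 0.0289). Acsl4 stood at -0.074 without RSL3 replicate 2 and at -0.0085 without RSL3 replicate 3. Removing the length and GC trends, an alternative chosen after seeing the data, gave 0.35 for Slc7a11 (adjusted p = 0.00930). Chac1, which degrades glutathione, went from 51.3 ± 0.79 to 57.0 ± 7.47 FPKM (adjusted p = 0.402). The iron regulatory gene Ireb2 stood at 7.47 ± 0.26 and 7.17 ± 1.65 FPKM (-0.072, adjusted p = 0.816), at 0.11 without RSL3 replicate 1 and at 0.038 without the trends. The ferritin light chain gene Ftl1 stood at 415 ± 130 and 419 ± 58.9 FPKM (0.059, adjusted p = 0.912), at -0.24 without DMSO replicate 3 and at -0.033 without RSL3 replicate 2. Ptgs2 was not listed in the tables.

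Of 8 tested genes in the list of reported ferroptosis markers 2 rose, Hmox1 and the stress-induced Ddit4 (0.33 ± 0.07, adjusted p = 0.0332; 0.0569 with median-ratio scaling). None fell, and 3 rose with adjustment over the list alone. The list was called higher (median 0.27, camera adjusted p = 0.00157; adjusted p = 0.225 with an estimated correlation). Sat1, which catabolises polyamines, stood 0.46 higher without passing (adjusted p = 0.0662). It passed with median-ratio scaling (adjusted p = 0.0327), quantile normalization (0.0328), length and GC trends removed (0.00380) and without RSL3 replicate 1 (0.0209). Without RSL3 replicate 1, 6 members rose, and 1 rose without DMSO replicate 1, 2 or 3 or without RSL3 replicate 3. Genes that defend against ferroptosis were not called as a list (camera adjusted p = 0.313). Of 20, 3 rose: the glutathione reductase gene Gsr (0.41), the glutathione synthesis gene Gclc (0.37) and Aifm2 (0.33), which regenerates ubiquinol. Adjusted over the list alone, 4 rose and 4 fell. The number that rose was 5 without RSL3 replicate 1, 1 without DMSO replicate 2 or RSL3 replicate 2, and 0 without any other single library. Genes that promote ferroptosis were not called either (adjusted p = 0.353), with 2 of 13 rising, Por (0.33) and the desaturase gene Fads2 (0.30). Over the list alone 3 rose and 1 fell, and between 0 and 4 rose without single libraries. Their median was -0.056 and their mean -0.033, while camera placed the list higher than other genes. In iron handling (adjusted p = 0.188) Hmox1 and Fth1 rose and the transferrin gene Trf fell by 1.13 on the log2 scale, out of 18 tested and with the same counts over the list alone. The fall was lost without DMSO replicate 2, DMSO replicate 3 or RSL3 replicate 3 and with the replicate block, and under the stricter filter 0 of 12 fell. Trf also belongs to the liver list, whose sum was 169 FPKM with DMSO and 76.9 FPKM with RSL3. Aifm2 and Trf were chosen after their values were seen.

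**Figure D2:**
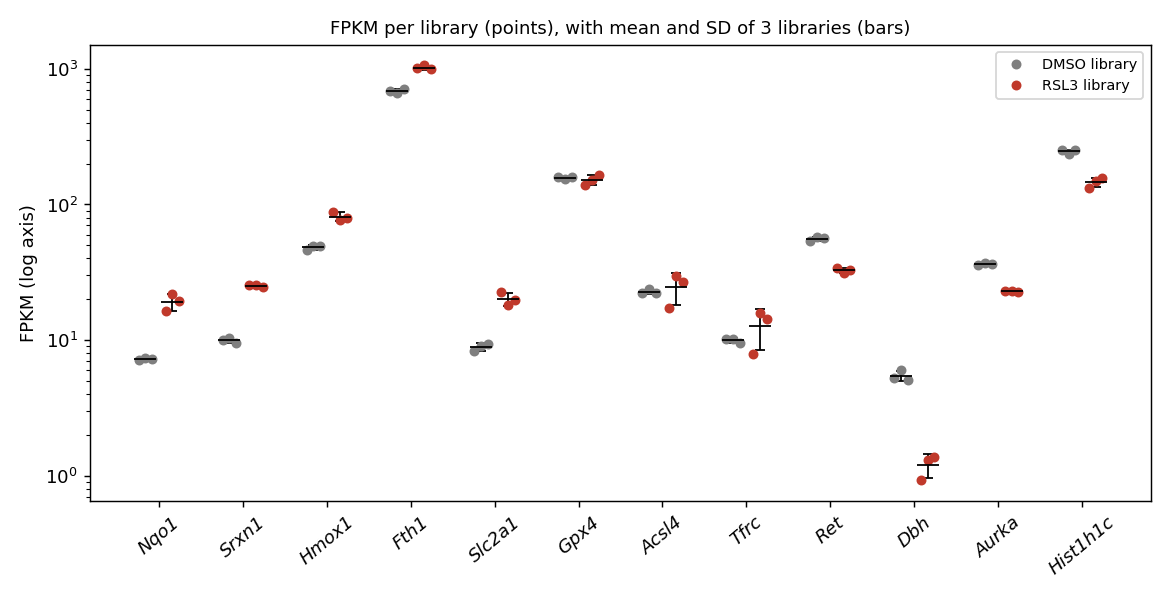
FPKM per library on a log axis for 12 named genes, DMSO in grey and RSL3 in red, with bars for the mean and SD of 3 libraries. Hmox1 and Fth1 were higher in every RSL3 library, whereas the groups overlapped for Gpx4, Acsl4 and Tfrc.

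Histone genes had the lowest median of the 31 tested lists. Of 25 replication-dependent histone genes, 21 fell and 0 rose (23 fell with adjustment over the list alone). The median log2 fold change was -0.69 (camera adjusted p = 7.34e-18; adjusted p = 0.225 with an estimated correlation). Hist1h2bn went from 351 ± 7.38 to 205 ± 10.7 FPKM (-0.77 ± 0.06, adjusted p = 0.00253). Hist1h1c, Hist1h2ae and Hist1h2ac fell by 0.75, 0.68 and 0.81 on the log2 scale, and these 4 genes passed in all 6 fits without a single library. The number that fell was 11, 13 and 11 without DMSO replicates 1, 2 and 3. Such transcripts largely lack poly(A) tails. The lncRNAs of the ribosomal RNA locus were 1.42 times as high with RSL3, and the liver list was lower in the same 3 libraries.

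Of 30 genes of G2 and mitosis, 18 fell and 0 rose, and 27 fell with adjustment over the list alone. The median log2 fold change was -0.45 (camera adjusted p = 4.66e-15; adjusted p = 0.225 with an estimated correlation). The mitotic kinase gene Aurka went from 36.4 ± 0.37 to 22.8 ± 0.27 FPKM (-0.65 ± 0.05, adjusted p = 0.00275). The checkpoint gene Bub1b fell by 0.56, Plk1 by 0.73 and Cdk1 by 0.56 on the log2 scale. Of these, Aurka and Bub1b passed in all 6 fits without a single library. In S phase genes 6 of 32 fell and 0 rose (7 fell over the list alone), with a median of -0.13 (camera adjusted p = 0.0113; adjusted p = 0.372 with an estimated correlation). The replication genes Mcm5, Cdc45 and Mcm10 fell by 0.43, 0.45 and 0.38, and Uhrf1, which maintains DNA methylation, by 0.33; each lost the call without at least 1 library. Left out singly, DMSO replicates 1, 2 and 3 and RSL3 replicate 3 left 3, 2, 2 and 3 falling G2 and mitosis genes and 0, 0, 0 and 1 falling S phase genes. The median of G2 and mitosis genes was -0.60 in RSL3 replicate 1 and -0.34 and -0.43 in replicates 2 and 3. The liver list was lower in the same 3 libraries.

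**Figure D3:**
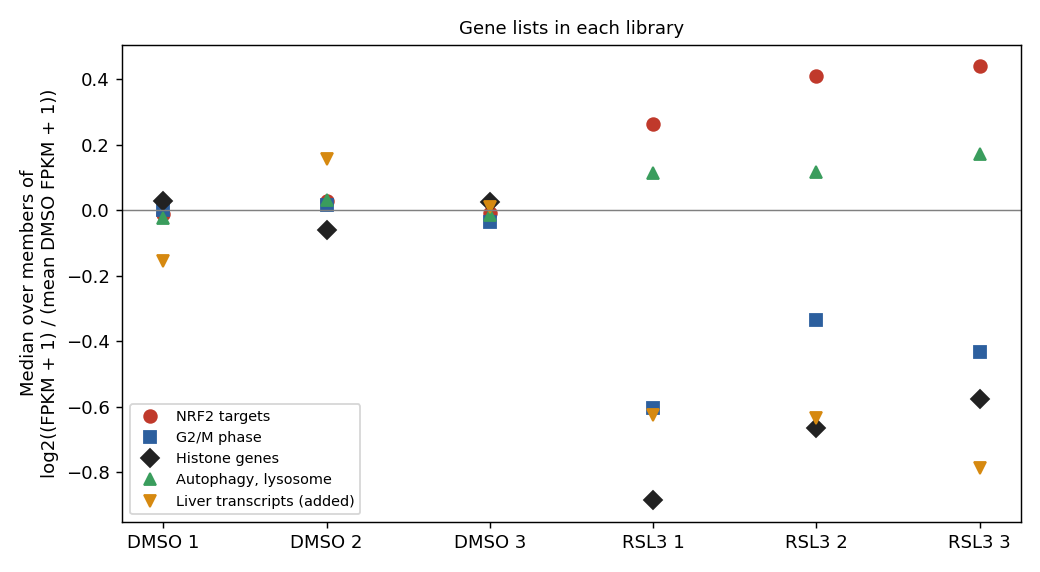
Median over the members of 5 gene lists of the log2 ratio of each library to the DMSO mean (FPKM + 1), with 1 symbol per list and library. All 3 RSL3 libraries lie above the DMSO libraries for NRF2 targets and below them for G2 and mitosis, histone and liver genes, the last list having been added after its values were seen.

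Of 31 genes of autophagy and lysosomes, 4 rose and 0 fell (7 rose over the list alone), with a median log2 fold change of 0.14 (camera adjusted p = 0.000255; adjusted p = 0.225 with an estimated correlation). Among them, the sialidase gene Neu1 rose by 0.56 ± 0.07 (adjusted p = 0.00725) and Gabarapl1 of the autophagosome by 0.38 ± 0.06 (adjusted p = 0.0167). The protease gene Ctsd went from 182 ± 3.91 to 250 ± 11 FPKM (adjusted p = 0.00731). Of 21 genes of the unfolded protein response 3 rose and 0 fell (5 rose over the list alone), with a median of 0.18 (camera adjusted p = 0.00107; adjusted p = 0.297 with an estimated correlation and 0.0661 by fry). Pdia6, Pdia4 and Creld2, which serve protein folding in the endoplasmic reticulum, rose by 0.63, 0.33 and 0.31. Sdf2l1 stood 0.27 higher without passing (adjusted p = 0.0519), and passed under the stricter filter (0.0425), after quantile normalization (0.0289), with trends removed (0.0174) and without RSL3 replicate 1. Neu1 and Pdia6 passed in all 6 fits without a single library. Without RSL3 replicate 1, 9 autophagy and lysosome genes and 8 unfolded protein genes rose. Without DMSO replicate 3, 2 and 1 did, and 1 unfolded protein gene rose without DMSO replicate 2 or RSL3 replicate 3.

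Lists of metal, glycolysis, heat shock and lipid genes were also called higher, and each of these calls ended in at least 1 fit without a single library. Among 5 metal-responsive genes the metallothionein gene Mt1 rose from 8.46 ± 0.25 to 17.9 ± 2.20 FPKM (log2 fold change 0.996 ± 0.09, adjusted p = 0.00376). Slc30a1 (0.46), Mt3 (0.46) and Slc39a10 (-0.46) did not pass, although all 3 did with trends removed, and Slc30a1 also under both scalings and without RSL3 replicate 1; over the list alone 3 rose and 1 fell. The metal list had a median of 0.46 and a camera adjusted p of 0.0323 (adjusted p = 0.254 with an estimated correlation). Its adjusted p was 0.0745 without DMSO replicate 2, 0.0758 without RSL3 replicate 1, 0.0512 without RSL3 replicate 2, 0.0581 with median-ratio scaling, 0.0658 with quantile normalization and 0.0618 with trends removed. Of 27 hypoxia and glycolysis genes 4 rose and 0 fell, and 4 rose over the list alone. They were the glucose transporter gene Slc2a1 (8.93 ± 0.57 to 20.1 ± 2.18 FPKM), Aldoa (0.59), Bnip3 (0.49) and P4ha1 (0.36). That list had a median of 0.12 and a camera adjusted p of 0.00779 (adjusted p = 0.372 with an estimated correlation; 0.0527 by fry, 0.0562 without RSL3 replicate 1). Of 17 heat shock genes the chaperone gene Hspa8 rose (0.54 ± 0.12, adjusted p = 0.0447), 0 fell, and 2 rose over the list alone. Hsph1 (0.36), Hspb8 (0.26) and Dnajb1 (0.16) did not pass, although Hsph1 and Hspb8 did after quantile normalization and with trends removed, and Hsph1 without RSL3 replicate 1. The heat shock median was 0.11 and the camera adjusted p 0.0357 (adjusted p = 0.372 with an estimated correlation; 0.154 by fry, 0.0512 without DMSO replicate 3, 0.161 without RSL3 replicate 2). In fatty acid and lipid droplet genes 3 of 21 rose and 1 fell (4 and 2 over the list alone), with a median of 0.07 and a camera adjusted p of 0.0399 (adjusted p = 0.460 with an estimated correlation). Its adjusted p was 0.0817 by fry, 0.0504 with the replicate block, 0.0527 with trends removed, 0.102 without DMSO replicate 1, and 0.0562, 0.0512 and 0.0541 without RSL3 replicates 1, 2 and 3. The lipid droplet coat genes Plin3 and Plin2 rose by 0.68 and 0.55 and Lpin1 by 0.33, while Acly, which makes cytosolic acetyl-CoA, fell by 0.29. The Acly call was lost with median-ratio scaling (adjusted p = 0.0551), after quantile normalization (-0.15, adjusted p = 0.214), without the variance trend (0.0700), with the replicate block (0.0964) and in 5 of the 6 fits without a single library (up to 0.177). Mt1, Slc2a1 and Plin3 passed in all 6 fits without a single library. Over these fits between 1 and 4 hypoxia and glycolysis genes, 0 and 3 heat shock genes, and 1 and 3 lipid genes rose.

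Nuclear genes of the respiratory chain were called lower as a list at the preset correlation, with 3 of 37 falling and 0 rising (11 falling over the list alone). Their median log2 fold change was -0.18 (camera adjusted p = 0.000255; adjusted p = 0.289 with an estimated correlation). The complex I subunit genes Ndufb8, Ndufa9 and Ndufs8 fell by 0.37, 0.32 and 0.29, and Cyc1 of complex III stood at -0.28 without passing (adjusted p = 0.0512), and passed under the stricter filter (0.0430) and with trends removed (0.00696). Ndufs8 did not pass with median-ratio scaling (adjusted p = 0.0545) or quantile normalization (0.0878). The nuclear list had 0 falling genes without any 1 DMSO library or RSL3 replicate 3, 8 without RSL3 replicate 1 and 7 without RSL3 replicate 2. The 13 mitochondrially encoded genes had a median of -0.37 with 0 passing, also over the list alone. The complex I gene mt-Nd2 stood at -0.69 (adjusted p = 0.0948), mt-Nd6 at -0.54, mt-Nd1 at -0.39 and mt-Nd5 at -0.38, and these 4 passed without RSL3 replicate 2, mt-Nd2 also with trends removed (-0.47). The mitochondrial list was called at a camera adjusted p of 0.0197 (adjusted p = 0.590 with an estimated correlation and 0.275 by fry). Its adjusted p was 0.0559 without DMSO replicate 1, 0.0758 without RSL3 replicate 1, 0.0614 without RSL3 replicate 3, 0.0528 with the stricter filter and 0.0624 after quantile normalization. With the length and GC trends removed it was 0.284.

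Among targets of the amino acid stress factor ATF4, 10 of 34 fell and 1 rose (17 and 2 over the list alone). The median log2 fold change was -0.23 and the mean -0.14 (camera adjusted p = 0.00608; adjusted p = 0.225 with an estimated correlation). Mthfd2, Aldh18a1 and Gpt2, enzymes of one-carbon, proline and alanine metabolism, fell by 0.42, 0.46 and 0.44. The secreted Stc2 fell by 0.45, and Ddit4 was the member that rose (0.33). The list had an adjusted p of 0.0827 after quantile normalization and 0.0512 without RSL3 replicate 2. The number that fell was 1, 0 and 1 without DMSO replicates 1, 2 and 3, 15 without RSL3 replicate 1 and 4 without RSL3 replicate 3.

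Of 8 tested genes for transmitter identity 3 fell and 0 rose, the same over the list alone. The median log2 fold change was -0.22 (camera adjusted p = 0.00608; adjusted p = 0.254 with an estimated correlation, and 0.0512 without RSL3 replicate 2). Among them, Dbh, which makes noradrenaline, went from 5.46 ± 0.48 to 1.21 ± 0.24 FPKM (-1.55 ± 0.11, adjusted p = 0.00230). The vesicular transporter gene Slc18a2 fell by 0.47 on the log2 scale. Hand2 stood at -0.25 (adjusted p = 0.192) and reached -0.36 without RSL3 replicate 1 (adjusted p = 0.00761), where 6 members fell. Genes of the response to retinoic acid were not called as a list (camera adjusted p = 0.521; median -0.017, mean 0.032), yet 4 of 11 passed. Cyp26b1, which degrades retinoic acid, rose from 74.9 ± 3.48 to 131 ± 12 FPKM, and the receptor gene Ret fell from 56.0 ± 1.85 to 32.6 ± 1.5 FPKM. Tgm2 and Rxra, chosen after their values were seen, rose by 0.63 and 0.38. Over the list alone 4 rose and 3 fell, and between 1 and 4 rose when single libraries were left out. Dbh, Cyp26b1 and Ret passed in all 6 of these fits. Genes of neuronal structure were not called (adjusted p = 0.611), with 4 of 26 falling, among them the growth cone gene Gap43 (-0.37) and the adhesion gene Ncam1 (-0.34). Over the list alone 2 rose and 6 fell, and between 0 and 4 fell without single libraries. The list's direction turned under the stricter filter, after quantile normalization and without RSL3 replicate 2. Of 16 ion channels and receptors of pain pathways 0 passed, also over the list alone (camera adjusted p = 0.675; median -0.019, mean -0.022, while camera placed the list higher).

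Among the other genes with the largest changes, Tsku, a secreted leucine-rich proteoglycan, rose from 2.03 ± 0.40 to 6.77 ± 0.93 FPKM (log2 fold change 1.36 ± 0.13, adjusted p = 0.00377). Vkorc1, which recycles vitamin K, rose 2.53-fold, from 8.29 ± 0.47 to 21 ± 0.64 FPKM (adjusted p = 0.00148). Lgals3, the gene of galectin-3, rose from 3.45 ± 0.33 to 7.59 ± 1.21 FPKM (0.94 ± 0.12, adjusted p = 0.00790). The transcription factor gene Sox12 fell from 8.63 ± 2.28 to 1.82 ± 0.45 FPKM (-1.75 ± 0.20, adjusted p = 0.00538). The remaining 7 largest falls were genes typical of liver or of the major urinary protein family: Mup7, Gm21320, Mup17, Fabp1, Alb, Mup3 and Mup15, with log2 fold changes from -1.93 to -1.62. Albumin mRNA (Alb) stood at 28.1 ± 5.21 FPKM with DMSO and 8.15 ± 3.48 FPKM with RSL3, and Fabp1 at 10.2 ± 1.13 and 2.27 ± 1.32 FPKM. The Mup genes are near-identical copies that share reads, so the value of any 1 of them is uncertain. Their 18 listed members summed to 101 FPKM with DMSO and 19.2 FPKM with RSL3. In the fits without a single library the adjusted p reached 0.10 for Alb, 0.141 for Mup15, 0.0943 for Mup7, 0.0769 for Mup17, 0.0741 for Gm21320 and 0.0557 for Fabp1. Mup3, Sox12, Tsku, Vkorc1 and Lgals3 passed in all 6.

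Of the other lists, selenoprotein genes were not called (camera adjusted p = 0.165), although 4 of 22 fell and 1 rose, the same over the list alone, and 2 fell without any 1 DMSO library. Selenoh fell by 0.75 on the log2 scale and Selenop, which is also on the liver list, by 0.83; both passed in all 6 fits. Immediate early genes (camera adjusted p = 0.0788) had 1 rise and 1 fall among 17, Jund (0.61) and Egr1 (-0.54; adjusted p = 0.0558 with median-ratio scaling and 0.0567 after quantile normalization), and 3 and 1 over the list alone. Without any 1 DMSO library, without RSL3 replicate 3 and with the replicate block 0 rose and 0 fell, and 2 rose and 2 fell without RSL3 replicate 1. Jund and Egr1 each passed in 2 of the 6 fits without a single library (adjusted p up to 0.105 and 0.118). At the preset correlation camera called this list without RSL3 replicate 2 (adjusted p = 0.0254), without RSL3 replicate 3 (0.0209) and under the stricter filter (0.0301). In the main fit with an estimated correlation its camera adjusted p was 0.607. In the interferon response (adjusted p = 0.205; median -0.024, mean 0.064) 2 of 11 rose, Ifi35 (0.56) and Bst2 (0.34), with 2 rising and 1 falling over the list alone. In membrane repair (adjusted p = 0.165) 2 of 18 rose, the annexin genes Anxa2 (0.54) and Anxa7 (0.39). In cholesterol synthesis (adjusted p = 0.186) 1 of 24 rose, Insig1 (0.34). In the proteasome (adjusted p = 0.423) Psmd4 (0.25) rose and Psmb2 (-0.36) fell among 31. Both lost the call with median-ratio scaling (adjusted p = 0.0650 and 0.0783) and without the variance trend (0.0771 and 0.0534), and with the replicate block. Psmb2 also lost it after quantile normalization (0.106) and with trends removed (-0.20, adjusted p = 0.109), and 0 proteasome genes fell under either scaling. The counts for membrane repair, cholesterol synthesis and the proteasome were the same over the list alone. Without single libraries between 0 and 2 interferon genes, 0 and 3 membrane repair genes, 0 and 1 cholesterol genes and 0 and 2 proteasome genes rose. Apoptosis genes (adjusted p = 0.137), p53 targets (adjusted p = 0.186) and inflammatory NF-kB targets (adjusted p = 0.611) had 0 of 21, 0 of 20 and 0 of 9 members passing, also over the list alone. Without RSL3 replicate 1, 2 apoptosis genes and 1 p53 target rose, and without RSL3 replicate 2, 1 apoptosis gene fell. Ribosomal protein genes had 0 of 74 passing, also over the list alone (camera adjusted p = 0.560; median -0.0036, mean -0.016, while camera placed the list higher). Without RSL3 replicate 1, 1 rose and 1 fell. At the preset correlation camera called the list higher after quantile normalization (adjusted p = 2.28e-06) and with the length and GC trends removed (adjusted p = 0.000589). In the main fit with an estimated correlation its camera adjusted p was 0.839.

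Markers of other cell types were too few to test as lists. Of 2 fibroblast markers Pdgfrb stood at -0.42 (adjusted p = 0.0527) and Fn1 at -0.32 (adjusted p = 0.0785), and 1 of the 2 fell under the stricter filter and after quantile normalization. The 2 astrocyte and 3 oligodendrocyte markers had medians of 0.25 and 0.24 with 0 passing (1 astrocyte marker rose without RSL3 replicate 1), and 0 macrophage or epithelial markers were tested. Over the list alone 2 fibroblast markers, 1 astrocyte marker (Sox9, 0.33) and 1 oligodendrocyte marker (Cnp, 0.24) passed. The 4 markers named here were chosen after their values were seen. Camera at the preset correlation called 15 of 31 lists, 8 higher and 7 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.165. By fry, 10 lists moved one way on balance and 26 changed in either direction.

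No lncRNA passed in the main fit: 0 of 798 had an adjusted p under 0.05 in limma, the smallest being 0.103. An unadjusted p under 0.05 was reached by 95, 55 higher and 40 lower. Of the 28 tested lncRNAs from the fixed list of well-studied ones, 0 passed over all lncRNAs, 5 had an unadjusted p under 0.05 and 2 passed with adjustment over the list alone. The snoRNA host gene Snhg5 went from 44.7 ± 2.58 to 25.6 ± 4.5 FPKM (log2 fold change -0.81 ± 0.15, list-alone adjusted p = 0.0109). Epb41l4aos went from 48.7 ± 1.76 to 69.3 ± 2.89 FPKM (0.50 ± 0.10, list-alone adjusted p = 0.0109). The groups did not overlap for either gene. Malat1, a nuclear speckle RNA, stood at 198 ± 10.9 and 296 ± 65.8 FPKM (0.55 ± 0.16, adjusted p = 0.254), and was the single lncRNA to pass without RSL3 replicate 1 (0.75, adjusted p = 0.0243). With the stricter filter 6 lncRNAs passed, Epb41l4aos higher and Snhg5, 1700120C14Rik, 1700048O20Rik, Gm42047 and Gm42743 lower. With median-ratio scaling 5 passed, all lower, among them Snhg5, Gm20628 and 3 of the same genes. All lncRNAs named here were chosen after their values were seen.

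CircRNAs are single-stranded rings made by back-splicing. Their number per library was 1592 ± 62.4 with DMSO and 1505 ± 155 with RSL3 (SD, n = 3; difference -87.3, two-sided exact permutation p = 0.6). The library with the fewest reads, RSL3 replicate 1, also had the fewest circRNAs (1329), and without it the difference was 0.5. Thinned to the same number of reads, an alternative chosen after seeing the data, the groups held 1423 ± 9.58 and 1425 ± 83.6 circRNAs. The thinned numbers were 1412, 1428 and 1429 with DMSO and 1329, 1484 and 1461 with RSL3, so that without RSL3 replicate 1 both RSL3 libraries lay above every DMSO library (difference 49.4, exact permutation p = 0.1, the smallest possible). Of 3168 circRNAs, 358 were seen in all 6 libraries and 810 in 1 library, and the median total was 6 reads over all libraries.

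No circRNA passed in limma, 0 of 1662 tested, with 129 at an unadjusted p under 0.05, 34 higher and 95 lower. The median log2 fold change over all tested circRNAs was -0.114. Its sign depended on the filter: without it, over all 3168 circRNAs, the median was 0.075. It stayed negative under the other limma alternatives (-0.056 with median-ratio scaling). Of the 3168, 726 were seen in no DMSO library and 588 in no RSL3 library. The groups did not overlap for 11.8% of them, where chance gives 10%. The RSL3 libraries held on average 0.81 times the back-splice reads of the DMSO libraries. What lowered the median of the circRNAs past the filter was not tested. The edgeR test of the recovered reads called 1 circRNA and gave 106 at an unadjusted p under 0.05. That circRNA was mmu_circ_0001730, with 0, 1 and 0 reads in the DMSO libraries and 17, 9 and 4 in the RSL3 libraries (adjusted p = 0.329 in limma and 0.0393 in edgeR). The other circRNAs named by the rule did not pass in either test. A ring from Rcc2 (chromosome 4, 140707951 to 140717200, plus strand) had 0, 0 and 0 reads with DMSO and 2, 7 and 14 with RSL3 (adjusted p = 0.556 in limma, 0.0745 in edgeR). The circRNA mmu_circ_0003712 had 0, 0 and 0 against 6, 6 and 3. A ring from Zfx (chromosome X, 94098283 to 94102380, minus strand) had 20, 15 and 11 reads with DMSO and 1, 3 and 3 with RSL3. There were 5, 10 and 21 against 0, 3 and 1 reads of mmu_circ_0001153, and 22, 10 and 11 against 1, 1 and 5 of mmu_circ_0008751. These 4 had an adjusted p of 0.556 in limma and 0.657 in edgeR. In simulated data with the same number of libraries and independent noise 14% of 4-fold changes were recovered.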

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

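The removal of length and GC trends, the fits without liver or histone genes and the thinning of circRNA reads were chosen after seeing the data; the other alternatives were fixed before. The count of mRNA genes changed RSL3 vs DMSO (676, 261 higher, 415 lower) stayed within 1.5 times under other pseudocounts, filters, scalings, the fit without a variance trend (576 to 693) and without liver and Mup genes (598) or histone genes (570). It moved to 253 (88 higher, 165 lower) with the replicate block and to 1747 (791 higher, 956 lower; 643 shared with the 676) with length and GC trends removed. It moved, by construction, to 51 (8 and 43) with a 2-fold threshold and 264 (79 and 185) with an unadjusted p and a 1.5-fold threshold. Leaving out single libraries gave 137 to 1276 genes (47 to 520 higher, 84 to 756 lower). Of these 6 fits 4 gave fewer than 676 and 2 gave more, 1276 without RSL3 replicate 1 (653 shared with the 676) and 725 without RSL3 replicate 2 (513 shared); the cause was not tested. For lncRNA genes changed RSL3 vs DMSO the count was 6 (1 higher, 5 lower) with the stricter filter, 5 (0 higher, 5 lower) with median-ratio scaling, 0 to 1 without single libraries and 0 under the other alternatives, and 2, 1 and 0 to 1 for the known lncRNA list. The stricter filter tests fewer genes (231), and the cause of the others was not tested. For circRNAs changed RSL3 vs DMSO edgeR gave 1 (1 higher), and every limma alternative 0. Gene list tests called 0 lists with an estimated correlation and 10 to 15 lists under the other alternatives, of which 10 to 15 were among the 15. Of the 77 named mRNAs that passed, 46 kept the call with the replicate block, 65 without the variance trend, 71 with median-ratio scaling, 73 with quantile normalization, 76 with length and GC trends removed and 31 to 76 without single libraries, and 0 turned. Directions turned only for results that did not pass, which tests little, since a result that passes is unlikely to turn. On the log2 scale, Gpx4 stood at 0.093 after quantile normalization and Ireb2 at 0.038 with trends removed. Without single libraries Ftl1 ranged from -0.24 to 0.21, Ireb2 from -0.18 to 0.11 and Acsl4 from -0.074 to 0.30. Lists turned, with these adjusted p, for neuronal structure at 0.844 (stricter filter) and 0.961 (quantile normalization), the proteasome at 0.605 (quantile normalization) and 0.808 (trends removed), ribosomal proteins at 0.935 (fry), NF-kB targets at 0.808 (trends removed) and pain channels at 0.935 (fry) and 0.518 (trends removed). Lists also turned without RSL3 replicate 2 (neuronal structure, 0.657), DMSO replicate 2 (ribosomal proteins, 0.988) and RSL3 replicate 1 (NF-kB targets, 0.822), within ranges of 0.0923 to 0.716, 0.193 to 0.988 and 0.336 to 0.822. For the number of circRNAs detected per library, RSL3 vs DMSO, the difference (-87.3) was -147 to 0.5 without single libraries and 1.57 after thinning, which equalises the reads. After thinning it was 4.24 without DMSO replicate 2, 4.43 without DMSO replicate 3, 49.4 without RSL3 replicate 1, and -28.1 to -3.96 without any other single library. For these turned results other than the circRNA number, the cause was not tested. The planned correlation with host genes was not run as planned, since the tables name no host gene. Read depth is unknown for FPKM, and circRNAs had a median total of 6 reads; what more reads would add was not tested.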

Other observations

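The gene lists of this part, the genes named only here and the tests on liver and histone transcripts were chosen after the values were seen. So were the share explained by GC content alone for RSL3 replicate 1, the slope on host genes and the removal of GC trends. The other tests on RSL3 replicate 1, the correlation with host genes and the other splits were written before their results. Lysosomal enzyme and membrane protein genes were also counted beyond those already named. Of 68 tested, 17 rose and 0 fell (median log2 fold change 0.20), and 10 of the 73 members and 3 of the 17 also stand on fixed lists. No p is given for the lists of this part, since members had been seen among the called genes when they were written. Gla, the galactosidase lost in Fabry disease, rose by 0.59, the arylsulfatase gene Arsa by 0.56, the cystine exporter gene Ctns by 0.59 and Creg1 from 22.8 ± 1.29 to 34.6 ± 1.40 FPKM (adjusted p = 0.00562). Between 3 and 30 rose when single libraries were left out (5, 5 and 3 without DMSO replicates 1, 2 and 3, and 30 and 5 without RSL3 replicates 1 and 3), 7 with the replicate block and 27 after quantile normalization. The peroxide-degrading enzyme gene Cat rose from 12.7 ± 1.0 to 23.3 ± 1.24 FPKM (0.83 ± 0.08, adjusted p = 0.00377).

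Of 28 noradrenergic and neuroblast genes, 11 fell and 0 rose (median -0.27); 15 of the 39 members and 5 of the 11 also stand on fixed lists. Of the 29 listed, 15 were lower in every RSL3 library, 1 was higher in every one and 13 overlapped. Chance gives 5% each way and 33% of all tested mRNAs did not overlap; as the list was written from called genes, this tests nothing. Besides Dbh and Ret, the serotonin receptor gene Htr3a went from 16 ± 1.29 to 7.17 ± 0.61 FPKM (-1.06 ± 0.09, adjusted p = 0.00286), the granin gene Chgb fell by 0.72, Insm1 by 0.75, the nicotinic receptor gene Chrna3 by 0.64 and Mycn by 0.62 on the log2 scale. Between 6 and 15 fell when single libraries were left out (6 without any 1 DMSO library), and 8 with the replicate block. After quantile normalization 10 fell and 1 rose. Of 61 ribosome biogenesis genes 12 fell and 0 rose (median -0.20), among them Fbl (-0.43), Polr1b (-0.39) and Nop56 (-0.35). The number that fell was 6 with median-ratio scaling, 4 after quantile normalization, 7 without the variance trend and 0 with the replicate block. It was 0 without any 1 DMSO library or RSL3 replicate 3, and 16 without RSL3 replicate 1.

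Liver-type transcripts, of which 52 of a list of 102 were present, had a median log2 ratio of means of -1.81, that is 3.50 times as much with DMSO, and 42 were lower in every RSL3 library. Chance gives 5% and 33% of all tested mRNAs did not overlap in either direction; the list was chosen for its falls, so the count does not test them. Read sharing within the Mup family does not account for it, since that median of -1.81 comes from a list without Mup genes. A candidate explanation is liver RNA present in varying amounts. Within groups the members moved together, with a mean pairwise correlation of 0.336 across genes. For 1000 random lists matched on mean FPKM the median was 0.0436 and the 95th percentile 0.126, and 0 of them reached 0.336. Genes regulated together in the cells would also move together, so this comparison does not single out mixed-in liver RNA. The correlation that camera estimated was 0.383 for the liver list and 0.411 for all histone clusters. With DMSO the most abundant members of the liver list were Alb (28.1 against 8.15 FPKM with RSL3), Fetub (27.9 against 27.2 FPKM, overlapping between groups) and Fabp1 (10.2 against 2.27 FPKM). Fetub is thus an abundant member that did not move with the list; 2 of the 102 members, Trf and Selenop, are on other lists. Whether RSL3 lowered such transcripts in the cells themselves cannot be told apart from this, because the 42 members lower in every RSL3 library are predicted by both; without liver and Mup genes the count of mRNA genes changed RSL3 vs DMSO was 598.

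RSL3 replicate 1 stood apart from the other RSL3 libraries. The SD over genes of its difference from the mean of the other 2 was 1.43 times that between those 2 (95% interval 1.35 to 1.52, median-ratio scaling). Equal and independent noise in these libraries would put the ratio below 1. The 95% intervals of this paragraph resample genes, which are not independent replicates, and hold no spread between libraries. A different library total shifts all genes alike, so it cannot by itself change an SD over genes. That holds by definition and needed no test. GC content explained a share of 0.422 of the variance of the difference of RSL3 replicate 1 (95% interval 0.398 to 0.452). Transcript length and GC content explained a share of 0.424 of the variance of its difference, almost all of it through GC. Yet the ratio stayed at 1.17 (1.10 to 1.27) after both fitted trends were removed, which argues against these fitted trends as the whole cause. A stronger response to RSL3 remains open: its difference correlated across genes with the change of the remaining RSL3 library at -0.143 one way and 0.0883 the other, so the test did not decide. Between the groups, length and GC explained a share of 0.0963 of the variance of the fold changes.

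Histone transcripts fell by a median of 0.69 on the log2 scale in the fixed list, and 57 of 65 genes of all histone clusters passed (38, 40 and 37 without DMSO replicates 1, 2 and 3). Of 7 polyadenylated histone variants 1 passed, 3 passed over the list alone, 0 had a rise, and 4 were lower in every RSL3 library (chance gives 5%; 33% of all tested mRNAs did not overlap in either direction). The variant that passed was lost with median-ratio scaling, quantile normalization, no variance trend, the replicate block, and without any 1 DMSO library or RSL3 replicate 3, and 2 passed without RSL3 replicate 1 or 2. Whether the 2 sets differ was not tested. Less carry-over of RNA without poly(A) tails cannot be told apart from a change in the cells. In poly(A)-selected libraries it would have lowered the ribosomal RNA locus too, which was 1.42 times as high with RSL3 and higher in every RSL3 library. If ribosomal RNA was depleted instead, which the labels leave unclear, that value would reflect the depletion. RNA that largely lacks tails was plentiful: the replication-dependent Hist1h2bn stood at 345 to 359 FPKM in the DMSO libraries. The median over all mRNAs was 6.33 to 6.57 FPKM in the same libraries. The 6 libraries also held 5226 to 9409 back-splice reads each. Read depth is unknown and no library of a known preparation was compared. These amounts therefore do not tell depletion from carry-over in selected libraries. Scaling does not account for the fall, since the median over all clusters nearer to 0 under the scaling alternatives was -0.61. Fewer cells in S phase may contribute, as the S phase list was called lower at the preset correlation (adjusted p = 0.0113), though not with an estimated one (adjusted p = 0.372). No member fell without any 1 DMSO library, and the list's median of -0.13 is far smaller than the fall of the histones.

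Before the data were examined, a correlation of circRNA and host gene changes was planned as a description, for tables that name the host gene. The hypothesis weighed here is that circRNAs follow the transcript of their host gene. Across 379 circRNAs of 306 host genes matched by coordinates, the log2 fold changes correlated at r = -0.0355 (permutation p = 0.490, 95% interval -0.126 to 0.0607) and rho = -0.0293 (permutation p = 0.568); circRNAs are not independent replicates. Counting noise holds such an r near 0 whether or not circRNAs follow their hosts, with a median of 8 reads per circRNA and a host fold change SD of 0.18, so the bound planned on r was wrong. In a count model following the host gives a slope of 1 times the reliability of the host fold changes (0.506). The slope was -0.18 (95% interval -0.96 to 0.83), which holds both 0 and 0.506, so the hypothesis stays open. For 39 circRNAs seen in all libraries r was -0.245 (permutation p = 0.133). 

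The 6 libraries can be divided into 3 against 3 in 10 ways, which is too few for a share under 0.05. In every division other than the real division, libraries of both groups stand on each side. A difference between the groups, whatever its cause, then adds to the spread within each side. Low mRNA counts in these divisions follow from that and do not test the count of the real division. The real division gave 676 mRNAs against at most 4 in the others (1 of the 10 with as many), 15 gene lists against at most 9 (1 of the 10), 0 lncRNAs against at most 1 (10 of the 10) and 0 circRNAs against at most 0 (10 of the 10).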
